A study of Mus musculus with 6 samples.

How the data were processed

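RNA from cultured mouse granulocytes was measured on 6 Affymetrix Mouse Gene 1.0 ST arrays, with 3 arrays per group. Per the labels' protocols, total RNA was extracted with Trizol and 300 ng was turned into biotinylated cDNA with the Encore Biotin Module. The deposited table holds 1 value for each of 34760 probe sets in each array. The values were taken as log2 values normalized between arrays by the authors: no header states the unit, but they run from 1.90 to 13.98, and another log base would put the brightest probe sets outside a scanner's range. The summarization, background correction and normalization are not given in the sources used here. Such values are relative, so a change in the total amount of mRNA per cell, which a block of transcription can bring, is not visible in them. Scanner files and detection p-values were not used here, so a low value was not read as absence, and differences of dim probe sets understate the change. The number of arrays limits the precision.

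Probe sets were named through the platform annotation supplied with the data, of which 21640 have 1 gene symbol, 1321 have several and 11799 are not listed. For 21553 of the 21640, the gene identifier was found in the reference gene table of assembly GRCm38.p6, which was used for current symbols, neighbouring genes and genomic spans only. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene was represented by the probe set with the highest mean over all 6 arrays, which left 19937 genes. In 954 genes with several probe sets, 10 had probe sets past the threshold in opposite directions, and 276 had some that passed and some that did not. Gapdh and Cdkn1a have only probe sets shared with other genes and Snhg1 and Snhg12 are not listed in the annotation used here, so none of them was tested.

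Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), without a filter on dim probe sets. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Both groups carry replicate numbers 1 to 3, which were not taken to pair the arrays. No batch is given in the labels, and no 2 arrays held identical values. Before the data were examined, 35 gene lists were fixed, 7 of them markers of other cell types or of eosinophils, basophils and mast cells. All were tested with limma's camera (preset correlation 0.01, adjusted over the 35 lists). Each list's median was also set against 10000 random lists matched on bins of genomic span and mean level. Random members were drawn independently, so correlation between a list's genes can make its percentile look too extreme. The percentiles were not adjusted over lists. List members were matched on symbol, or on an older symbol that belongs to a single gene.

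The genes to be named were also fixed beforehand by rule. They are the 10 largest rises and 10 largest falls past the threshold whose groups do not overlap, without clone names, small RNAs and olfactory or vomeronasal receptors. To these come up to 4 members of each list with the smallest p, and a fixed set of NMD-linked, stress and reference genes. A gene named outside the rule is marked as such. In simulated data with the means and variances of these arrays and 200 changed genes among 19937, the test recovered 56% of the changes of 0.5 and 97% of the changes of 1 on the log2 scale, and 5.56% of its calls were false. In a second simulation with 1 shifted list, that list was called and so was 1 of 34 unshifted lists.

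The settings varied were the replicate number as a block, quantile normalization, centring each array on its median, 2 filters on dim genes, the mean of a gene's probe sets, every probe set tested, eBayes without trend or with robust variance, array weights, each array left out in turn, and, for the lists, camera with an estimated correlation and fry.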

Results

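Granulocytes from C57BL/6J mice were profiled on 6 Affymetrix Mouse Gene 1.0 ST arrays, 3 from cells labelled caffeine-plus and 3 from cells labelled caffeine-minus. Caffeine inhibits the PI3K-like kinases, among them SMG1, whose phosphorylation of UPF1 drives nonsense-mediated decay (NMD), the pathway that destroys mRNAs carrying premature stop codons. Per the labels' protocols, cultures received 15 mM caffeine for 4 hours and were washed 2 times. They were then kept for 4 hours in 2 µg/ml actinomycin D, an inhibitor of transcription, either with caffeine or alone. Read this way, both groups had caffeine first and differed in whether it stayed during the transcription block, although the caffeine-minus samples are labelled as not treated with it. The series asks which transcripts accumulate when NMD is inhibited, and the comparison gives those that differed with caffeine during the transcription block. NMD activity itself was not measured. The median log2 value of an array was between 6.49 and 6.60 over 34760 probe sets, and arrays of one group correlated at r = 0.986 to 0.992 (Pearson, across probe sets) against 0.959 to 0.965 between groups. The first principal component held 81.7% of the variance across arrays and separated the groups, with the caffeine-plus arrays between -34.2 and -32.7 and the caffeine-minus arrays between 32.3 and 34.2. Differences below are caffeine-plus minus caffeine-minus on the log2 scale with their standard errors, n = 3 arrays per group, tested with limma and Benjamini-Hochberg adjustment. Nothing in the labels states whether the replicates came from separate animals or cultures, so p-values measure the spread between these arrays, which may be technical.

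Of 19937 genes, 3229 were higher and 4325 lower in the caffeine-plus cells (limma adjusted p under 0.05), and 525 were higher and 629 lower by at least 2-fold. Among the rises, Zcchc7, which encodes a zinc finger protein of the nuclear RNA surveillance machinery, was 6.82-fold higher (log2 difference 2.77 ± 0.07), with a log2 level of 10.10 ± 0.05 (SD, n = 3) against 7.33 ± 0.06 (SD, n = 3). Ifrd1, a transcriptional co-regulator, was 6.25-fold higher, and the orphan nuclear receptor gene Nr4a1 was 6.14-fold higher. The other genes of the 10 named rises were Ppp4r3a, a regulatory subunit of protein phosphatase 4 (5.47-fold), the receptor gene P2ry10 (4.79-fold), the small GTPase gene Gem (4.74-fold), Kctd6 (4.67-fold), the RNA helicase gene Ythdc2 (4.4-fold), the tyrosine phosphatase gene Ptpn2 (4.36-fold) and Msantd2 (4.29-fold). A second, dimmer probe set was 3.68-fold higher for Zcchc7 and gave a log2 difference of 0.17 ± 0.20 for Ptpn2.

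Among the falls, Amy1, the salivary amylase gene, was 16.2-fold lower in the caffeine-plus cells (log2 difference -4.02 ± 0.10), with a log2 level of 6.07 ± 0.18 (SD, n = 3) against 10.09 ± 0.10 (SD, n = 3). Zfp389 was 10.2-fold lower and Omg, the gene of an oligodendrocyte myelin glycoprotein, 10.1-fold lower. The span of Omg lies within that of Nf1 in the reference annotation. Zmat1 was 9.37-fold, Ankrd7 8.18-fold and Fam136a 7.30-fold lower. Apon was 6.31-fold, Trappc2l 5.46-fold, the bitter taste receptor gene Tas2r135 5.31-fold and Fibp 5.28-fold lower. The spans of Trappc2l and Fibp overlap those of Galns and Ctsw, and those of Ifrd1 and Ppp4r3a among the rises overlap Mir1938 and D130020L05Rik, so signal in these probe sets is uncertain in its gene. In all, 13 genes were higher and 56 lower by at least 4-fold. These counts include olfactory receptor genes, which the naming rule left out. Olfr1420, picked out after its value was seen, fell by more than Amy1 (log2 difference -4.12 ± 0.12). Of 1027 measured olfactory receptor genes 46 fell and 23 rose.

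Transcripts of the NMD machinery, several of which are themselves known NMD targets, rose together. Of 7 measured genes of the list, 6 rose, none fell and 1 did not pass the test, with a median log2 difference of 0.78. The kinase gene Smg1 was 2.35-fold higher (log2 difference 1.24 ± 0.06), Upf2 2.03-fold, the phosphatase adaptor gene Smg5 2.02-fold and the endonuclease gene Smg6 1.51-fold. Upf1 differed by 0.26 ± 0.09 (limma adjusted p = 0.038), and its call was lost without caffeine-plus array 1 (adjusted p = 0.093) or 2 (0.22) and without caffeine-minus array 2 (0.088) or 3 (0.066). It was also lost when every probe set was tested (0.076). Over 16 alternative settings its adjusted p ran from 0.0074 to 0.22. The list was higher than other genes by camera with a preset correlation of 0.01 (adjusted p = 0.0001), and adjusted p = 0.21 with an estimated correlation. In the estimated setting camera takes its degrees of freedom from the 6 arrays, so every list loses power there. For this list the estimate was -0.014, below the preset value, so a stronger correlation did not cost it the call. Adjusted over the list alone, 6 genes were again higher. The exon junction complex list had 4 members higher and 1 lower of 9 (camera adjusted p = 0.023, adjusted p = 0.26 with an estimated correlation), among them Rnps1 (2.00-fold higher) and Casc3 (1.89-fold higher), and adjusted over the list alone the counts were the same. The call was lost after quantile normalization (adjusted p = 0.095) and among genes above the median level (0.086), with a range of 0.019 to 0.095 over 10 alternatives.

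Host transcripts of small nucleolar RNAs (snoRNAs) are spliced RNAs degraded by NMD. Snhg16 was 4.13-fold higher and Snhg5 3.85-fold higher (log2 difference 1.94 ± 0.05), while Snhg17 differed by 0.16 ± 0.11 (adjusted p = 0.31). Snhg11 (0.05 ± 0.10) and Snhg15 (-0.06 ± 0.10), the other measured host genes besides Gas5, did not pass either and were picked out after their values were seen. Gas5, a well known NMD-sensitive host gene, had 4 probe sets that disagreed. Its brightest, 10351026, differed by 0.07 ± 0.04 (limma adjusted p = 0.22), with group means of 13.03 ± 0.06 (SD, n = 3) and 12.96 ± 0.04 (SD, n = 3). After quantile normalization it differed by 0.14 and passed (limma adjusted p = 0.0046), so 3 of 6 host genes then rose. Over 16 alternatives the limma adjusted p of Gas5 ran from 3.2e-09 to 0.58. The low end came from the mean of its 4 probe sets, not from the brightest alone. The other Gas5 probe sets, 10351037, 10351035 and 10351039, were 2.5-fold, 2.78-fold and 4.37-fold higher, with limma adjusted p = 9.1e-06, 5.3e-05 and 0.00034 in a fit of every probe set. Whether each Gas5 probe set covers exons of the host RNA or the snoRNAs within its introns is not known here. With each gene at its brightest probe set, 2 of the 6 measured host genes rose and none fell (camera adjusted p = 0.022, adjusted p = 0.25 with an estimated correlation), a call lost among genes above the median level (adjusted p = 0.074, range 0.013 to 0.074 over 10 alternatives). Of 51 snoRNA genes themselves, most of which lie in introns of host genes, 28 rose and 2 fell, with a median of 0.36 (camera adjusted p = 9.5e-07, adjusted p = 0.26 with an estimated correlation). Snora41 was 3.35-fold, Snord22 3.21-fold and Snora44 2.86-fold higher. Adjusted over the list alone, the counts were the same for both lists.

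**Figure D1:**
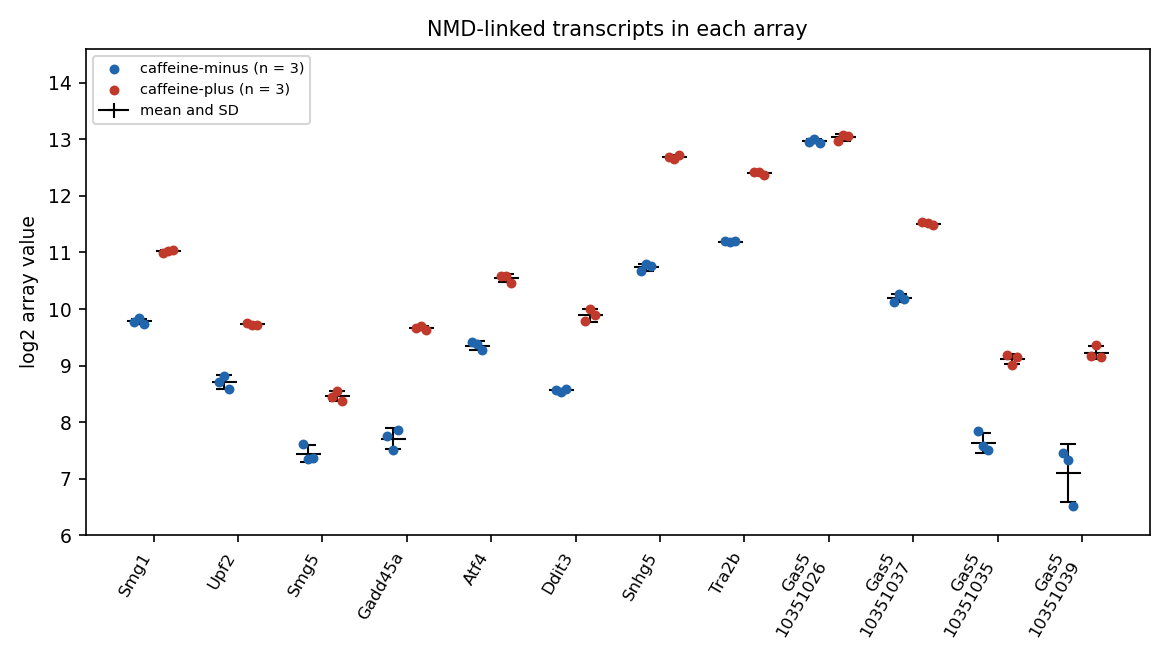
Log2 array values of 8 NMD-linked genes and of the 4 Gas5 probe sets (horizontal axis) in the 3 caffeine-minus arrays (blue) and the 3 caffeine-plus arrays (red), with the mean and SD of each group. The groups do not overlap for any item except Gas5 probe set 10351026, whose group means are 12.96 and 13.03. All 8 genes were higher past the limma threshold, so their lack of overlap reflects the choice of genes. NMD-linked genes that did not pass, such as Snhg17, or that fell, such as Chac1, are not shown.

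Stress genes of the ATF4 pathway, many of which have been reported as NMD targets, were higher as a list, with 16 of 28 rising, 4 falling and a median of 0.44 (camera adjusted p = 0.00013, adjusted p = 0.25 with an estimated correlation). Gadd45a, a growth arrest gene, was 3.87-fold higher (log2 difference 1.95 ± 0.09). The transcription factor genes Atf3, Ddit3 and Atf4 were 3.10-fold, 2.51-fold and 2.28-fold higher, and Gadd45b was 2.27-fold higher. Chac1 and Gabarapl1 went the other way, at 1.63-fold and 1.73-fold lower, and were picked out after their values were seen. Adjusted over the list alone, 17 were higher and 6 lower. Among cytosolic tRNA synthetases 10 of 18 rose and 5 fell, whether adjusted over all genes or over the list alone, and 3 fell with arrays centred on their medians. This list's call (camera adjusted p = 0.034, adjusted p = 0.53 with an estimated correlation) was lost without caffeine-plus array 2 (adjusted p = 0.071), without caffeine-minus array 3 (0.084), after quantile normalization (0.084) and among genes above the median level (0.11), with a range of 0.017 to 0.11 over 10 alternatives. Iars was 1.68-fold and Cars 1.66-fold higher, and Sars was 1.44-fold lower.

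Splicing factors with NMD-coupled isoforms were higher as a list. Of 37 measured, 28 rose, 3 fell and 6 did not pass the test, with a median of 0.46 (camera adjusted p = 1.4e-09, adjusted p = 0.26 with an estimated correlation), and adjusted over the list alone the counts were the same. Srsf4 was 2.97-fold higher, Tra2b 2.31-fold (log2 difference 1.21 ± 0.04), Hnrnpdl 2.18-fold, Tra2a 2.08-fold, Srsf3 1.85-fold and Srsf2 1.41-fold. Of the 2 dimmer Srsf3 probe sets, 10443459 was 1.80-fold higher and 10424379 gave a log2 difference of 0.00 ± 0.16. Srsf5, counted among the rises by its brightest probe set and picked out after its values were seen, also had a probe set that fell. Genes of general mRNA decay split, with 21 of 38 rising and 10 falling (21 and 11 when adjusted over the list alone). The deadenylase subunit gene Pan3 was 2.20-fold higher, Cnot4 and Cnot1 of the CCR4-NOT complex were 1.94-fold and 1.86-fold higher, and Btg1 was 1.96-fold higher (camera adjusted p = 0.00065 for the list, adjusted p = 0.28 with an estimated correlation). The arrays measured each gene as a whole and do not separate NMD-sensitive from productive isoforms.

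Lmnb1, the lamin B1 gene and a gene known for intron retention in granulocytes, was 1.26-fold higher (log2 difference 0.33 ± 0.07, limma adjusted p = 0.0014). Its log2 level was 9.55 ± 0.02 (SD, n = 3) in the caffeine-plus cells and 9.22 ± 0.11 (SD, n = 3) in the caffeine-minus cells. In the nuclear lamina and envelope list 12 of 19 genes rose and 3 fell, with a median of 0.33 (camera adjusted p = 0.0034, adjusted p = 0.26 with an estimated correlation), and adjusted over the list alone the counts were the same. The nucleoporin genes Nup98 and Nup153 were 2.03-fold and 1.63-fold higher, Lemd3 was 1.96-fold higher, and the emerin gene Emd was 1.72-fold lower. In the list of PI3K-like kinases and their partners 7 of 13 rose and 2 fell, adjusted over the list alone as well (camera adjusted p = 0.0077, adjusted p = 0.26 with an estimated correlation). Mtor was 2.5-fold, Ruvbl1 1.72-fold and Atm 1.71-fold higher.

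Genes induced through cAMP and CREB had the highest median of all 35 lists, 0.93. Caffeine inhibits the phosphodiesterases that degrade cAMP. Of 24 measured genes 19 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 5.8e-12, adjusted p = 0.16 with an estimated correlation). Besides Nr4a1, Gem and Atf3, the receptor gene Nr4a2 was 2.51-fold higher. Of 30 immediate early genes, whose mRNAs are short-lived, 19 rose and 2 fell (20 and 3 when adjusted over the list alone), with Rgs1 3.60-fold, Egr1 3.00-fold and the phosphatase gene Dusp1 2.61-fold higher (camera adjusted p = 6.5e-08, adjusted p = 0.25 with an estimated correlation). The lists shared 5 genes, and 14 of the other 25 immediate early genes rose. Of 20 listed genes from families that hold direct targets of methylxanthines, 15 phosphodiesterase and calcium release channel genes were measured and no adenosine receptor gene. Not every listed member need be a target itself. Of the 15, 5 rose and 1 fell, adjusted over the list alone as well (camera adjusted p = 0.017, adjusted p = 0.25 with an estimated correlation). All 5 that rose were phosphodiesterase genes, with Pde8a 2.17-fold, Pde4b 2.15-fold, Pde7a 2.06-fold and Pde3b 1.96-fold higher. Of these 5, all but Pde8a are also in the cAMP and CREB list, so the 2 results are not separate.

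**Figure D2:**
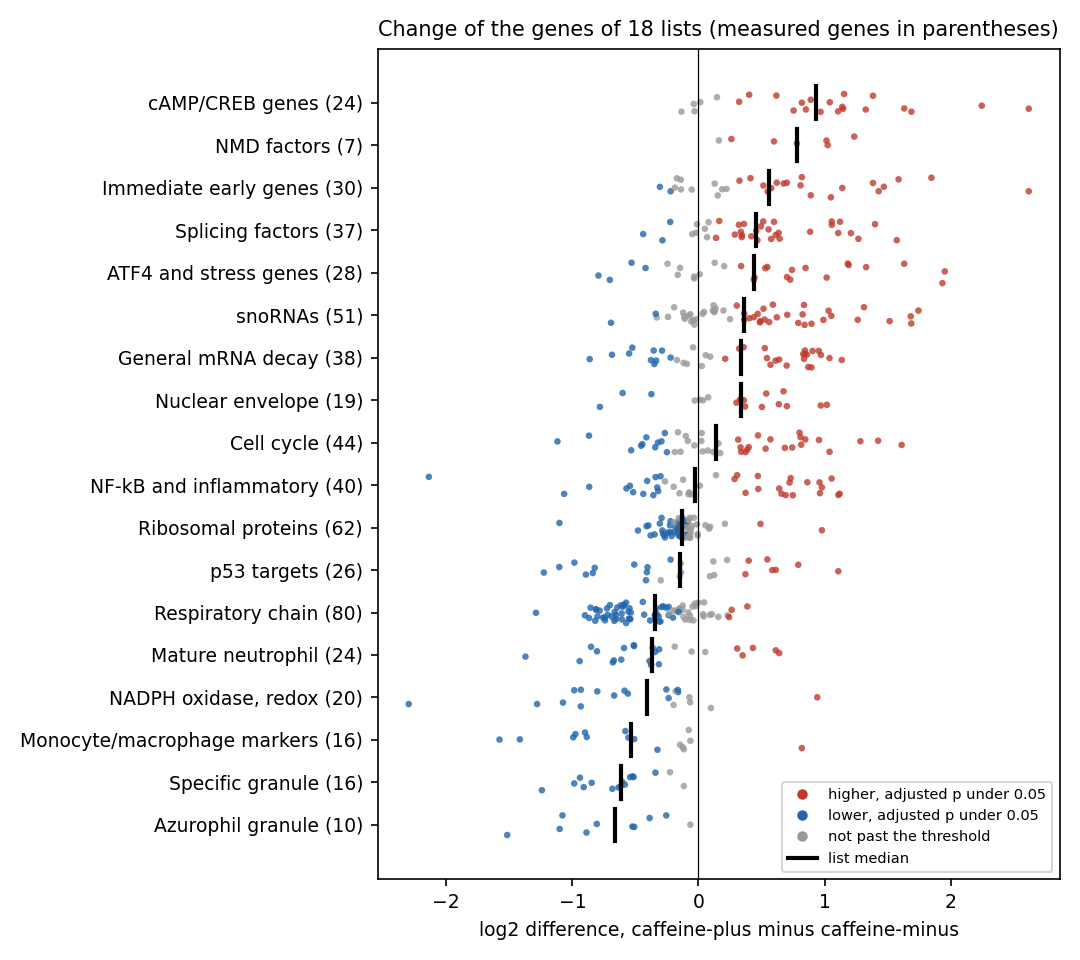
Log2 difference (caffeine-plus minus caffeine-minus, horizontal axis) of each measured gene in 18 of the gene lists (vertical axis), with genes past the limma threshold in red (higher) or blue (lower), others in grey, and the list median as a black bar. List medians run from 0.93 for cAMP and CREB genes to -0.67 for the azurophil granule list.

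Granule lists, which follow stages of granulocyte maturation, were lower in the caffeine-plus cells. Of 10 genes in the azurophil granule list 9 fell and none rose, with a median of -0.67 (camera adjusted p = 3.5e-05, adjusted p = 0.25 with an estimated correlation). The cytosolic protease inhibitor gene Serpinb1a was 2.86-fold lower, the neutrophil elastase gene Elane 2.14-fold lower (log2 difference -1.10 ± 0.05), Cst7 2.11-fold lower and the cathepsin C gene Ctsc 1.85-fold lower. The azurophil list also holds genes whose proteins are not granule contents, Igsf6, Ms4a3, Clec11a and Serpinb1a, all of which fell except Clec11a. Of 16 genes in the specific granule list 14 fell and none rose, with a median of -0.61 (camera adjusted p = 9.5e-07, adjusted p = 0.25 with an estimated correlation). Haptoglobin (Hp) was 2.36-fold, Pglyrp1 1.92-fold, lysozyme (Lyz2) 1.88-fold and Ngp 1.80-fold lower. That list also holds Ltb4r1 and Ly6g, genes of surface proteins, which fell. Igsf6, Ms4a3, Clec11a, Ltb4r1 and Ly6g were picked out after their values were seen. Adjusted over the list alone, the counts of both lists were the same. Of 24 mature neutrophil genes 16 fell and 5 rose (17 and 5 when adjusted over the list alone), with Slpi 1.92-fold, Pygl 1.80-fold, Mmp8 1.75-fold and S100a8 1.59-fold lower. That call (camera adjusted p = 0.015, adjusted p = 0.50 with an estimated correlation) was lost among genes above the median level (adjusted p = 0.065, range 0.0055 to 0.065 over 10 alternatives). The myeloid transcription factor list did not pass (camera adjusted p = 0.060, adjusted p = 0.26 with an estimated correlation), with 11 of 28 higher and 5 lower (11 and 8 when adjusted over the list alone), but it passed without caffeine-plus array 1 (0.0499) or 3 (0.035), with a range of 0.035 to 0.29 over 10 alternatives. Its members with the smallest p were Egr1, Id2 (2.65-fold higher), Klf6 (1.75-fold higher) and Max (1.72-fold higher).

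Among 7 lists of markers of other cells that a granulocyte preparation could hold, or of eosinophils and basophils, which are granulocytes themselves, 3 were lower. Of 16 monocyte and macrophage markers 10 fell and 1 rose, with a median of -0.53 (camera adjusted p = 0.0019, adjusted p = 0.26 with an estimated correlation). Ccr2 was 2.98-fold, Ly86 2.67-fold and Ctss 1.97-fold lower, while Cd68 was 1.77-fold higher. Of 13 dendritic cell markers 9 fell and none rose (camera adjusted p = 0.011, adjusted p = 0.26 with an estimated correlation), with Siglech 1.59-fold and H2-Ab1 1.42-fold lower. Of 13 eosinophil, basophil and mast cell markers 4 fell and 1 rose (5 and 1 when adjusted over the list alone), with the basophil protease gene Mcpt8 2.88-fold, Ms4a2 2.28-fold and Prg2 1.55-fold lower and Kit 1.22-fold higher. That call (camera adjusted p = 0.038, adjusted p = 0.29 with an estimated correlation) was lost without caffeine-plus array 3 (adjusted p = 0.071), without caffeine-minus array 1 (0.086) and among genes above the median level (0.063), with a range of 0.013 to 0.086 over 10 alternatives. Megakaryocyte markers (3 of 8 lower, 0 higher, camera adjusted p = 0.077), B cell markers (3 of 13 lower, 0 higher, camera adjusted p = 0.32), T and NK cell markers (0 of 12 past the limma threshold and 2 at an unadjusted p under 0.05, camera adjusted p = 0.43) and erythroid markers (2 of 11 higher, 2 lower, camera adjusted p = 0.69) did not pass as lists. Within these, Cd79b was 3.29-fold and Ppbp 2.11-fold lower, Alas2 was 1.57-fold lower and Tfrc 1.41-fold higher. The T cell genes Cd3d and Gzma differed by 0.24 ± 0.11 and 0.25 ± 0.11. Both passed when arrays were centred on their medians (limma adjusted p = 0.029 and 0.037, ranges 0.029 to 0.33 and 0.037 to 0.40 over the alternatives). Cd3d also passed after quantile normalization (limma adjusted p = 0.045). Apart from the eosinophil list, the counts of these marker lists adjusted over the list alone were the same.

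Nuclear genes of the respiratory chain and ATP synthase fell widely. Of 80 measured, 53 fell and 3 rose (56 and 4 when adjusted over the list alone), with a median of -0.34 (camera adjusted p = 2.7e-08, adjusted p = 0.25 with an estimated correlation). Ndufb9 was 2.44-fold lower, Ndufa3 1.76-fold, Atp5d 1.74-fold and Atp5h 1.67-fold lower. In the NADPH oxidase and oxidative defence list 14 of 20 fell and 1 rose, adjusted over the list alone as well (camera adjusted p = 0.00022, adjusted p = 0.26 with an estimated correlation). The quinone reductase gene Nqo1 was 4.92-fold lower, and the oxidase subunit genes Ncf1 and Cyba were 2.43-fold and 2.11-fold lower. Gclc, which encodes a subunit of the enzyme that begins glutathione synthesis, was 1.92-fold higher. Of 62 ribosomal protein genes 34 fell and 2 rose (36 and 2 when adjusted over the list alone), with a median of -0.13. Against random lists matched on genomic span and level, whose median was -0.30, the ribosomal median was higher rather than lower (percentile 98.7). Rps21 was 1.39-fold and Rplp1 1.27-fold lower, Rpl12 was 1.97-fold higher and Rpl7l1 2.15-fold lower. The list was matched by name, so it also holds genes of ribosomal-like proteins such as Rpl7l1. The ribosomal call (camera adjusted p = 0.020, adjusted p = 0.26 with an estimated correlation) was lost without caffeine-plus array 3 (adjusted p = 0.070), without caffeine-minus array 2 (0.062) and after quantile normalization (0.10), with a range of 0.010 to 0.10 over 10 alternatives. With arrays centred on their medians, 16 ribosomal protein genes fell. Actb, often used as a reference gene, was 1.5-fold lower (log2 difference -0.59 ± 0.04).

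Cell cycle genes moved in both directions, with 20 of 44 higher and 11 lower (20 and 12 when adjusted over the list alone) and a median of 0.14. The mitotic kinase gene Cdk1 was 3.05-fold higher, the centromere and spindle motor genes Cenpe and Kif11 were 2.43-fold and 2.06-fold higher, and the cyclin gene Ccnd2 was 2.17-fold lower. The call (camera adjusted p = 0.013, adjusted p = 0.58 with an estimated correlation) was lost without caffeine-minus array 3 (adjusted p = 0.069), after quantile normalization (0.074) and among genes above the median level (0.071), with a range of 0.0032 to 0.074 over 10 alternatives. NF-kappaB and inflammatory genes, many of which have short-lived mRNAs, did not pass as a list (camera adjusted p = 0.14), with 18 of 40 higher and 13 lower, adjusted over the list alone as well. Its median was -0.02, while its mean was 0.10 and the test's direction was up. The chemokine genes Ccl9 and Ccl3 were 4.4-fold and 2.09-fold lower, while the cyclooxygenase gene Ptgs2 and the NF-kappaB subunit gene Rel were 2.16-fold and 2.08-fold higher. The p53 target list did not pass either (0.56), with 7 of 26 higher and 11 lower (8 and 12 when adjusted over the list alone). Ei24, Ddb2 and Trp53inp1 were 2.34-fold, 2.15-fold and 1.77-fold lower, and Plk3 and Mdm2 were 2.16-fold and 1.5-fold higher.

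No shift passed for BCL2 family and caspase genes (camera adjusted p = 0.39, 6 of 27 higher and 12 lower), interferon response genes (0.67, 5 of 25 higher and 7 lower), glycolysis genes (0.56, 4 of 19 higher and 7 lower), proteasome genes (0.69, 11 of 39 higher and 14 lower) or histone genes (0.54, 2 of 31 higher and 7 lower). Adjusted over the list alone, these counts were 7 higher and 12 lower, 5 and 10, 4 and 7, 11 and 15, and 2 and 4. With arrays centred on their medians, 4 interferon response genes and 4 histone genes fell. Single members still changed. The pro-apoptotic gene Bcl2l11 and the survival gene Mcl1 were 2.51-fold and 1.63-fold higher, and Bak1 was 1.54-fold lower. Ifitm1 and Ifitm3 were 1.98-fold and 1.83-fold lower and Mx2 was 3.47-fold higher. Among glycolysis genes, Tpi1 and Pgam1 were 2.17-fold and 1.84-fold lower and the glucose transporter gene Slc2a1 and the hexokinase gene Hk2 were 1.94-fold and 1.93-fold higher. Psmb9 was 1.91-fold lower and Psmc6 1.86-fold higher, and the histone gene H2bc21 was 2.66-fold lower. In total 23 of the 35 lists passed with the preset correlation, 14 higher and 9 lower, and 0 passed with an estimated correlation by camera, where 5 had an unadjusted p under 0.05. That setting has low power with 6 arrays, so its 0 does not show that correlation between genes explains the calls. The estimates for NMD factors (-0.014) and snoRNA host genes (-0.13) were below the preset 0.01, and these lists lost their calls as well. The median estimate over the 35 lists was 0.116, above the preset, with 0.31 for splicing factors and 0.24 for specific granule genes. For such lists the preset p-values rest on a lower correlation than was estimated, so an effect of correlation is not excluded. Of the 23 lists that passed with the preset correlation, the medians of 6 did not stand apart from random lists matched on genomic span and level (two-sided, at 0.05). By percentile among such lists, these were cell cycle genes (97.2), the exon junction complex (83.6) and genes of methylxanthine target families (81.1). The others were PI3K-like kinases (80.1), tRNA synthetases (72.4) and eosinophil, basophil and mast cell markers (15.9). Ribosomal protein genes, called lower by camera, stood apart in the opposite direction (98.7). By fry, which tests each list without comparing it with other genes, 31 lists passed.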

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

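The tests of inflammatory genes, of other cell types' markers and of ribosomal protein genes in this part were chosen only after the results they bear on were seen.

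Probe sets without a gene in the annotation, which no comparison above uses, carried signal of their own. In a limma fit of every probe set, 1200 of the 6573 that are numbered before the first listed probe set were higher in the caffeine-plus cells and 632 were lower, with a largest log2 difference of 4.27. Of the 5226 unlisted probe sets numbered after it, 330 were higher and 678 lower. Whether these probe sets measure exons, introns or controls of the array is not known here, so their counts are not counts of genes.

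Among NMD-linked transcripts, NMD factors and splicing factors were higher as lists with the preset correlation but not with an estimated one (adjusted p = 0.21 and 0.26), while 4 of 6 snoRNA host genes did not pass, among them Gas5 at its brightest probe set, which passed after quantile normalization (adjusted p = 0.0046, 3 of 6 host genes higher). The medians of NMD factors and splicing factors lay at percentiles 99.2 and 99.97 of 10000 random lists matched on genomic span and level. These values argue against a trend with span and level for both lists, but it stays open for the exon junction complex list (83.6). Percentiles here and below leave out correlation between a list's genes and were not adjusted over the 35 lists, so they can look too extreme. For that Gas5 probe set, though not for Snhg11, Snhg15 and Snhg17 at log2 levels of 6.29 to 7.47, a ceiling that compresses changes stays open: 1 of 54 genes within 0.5 of its log2 level (1.85%) moved by 0.5 or more, against 34.7% of genes above the median level. Smaller changes were registered there, since 32 of the 54 (59.3%) passed the limma threshold, and array maxima reached 13.98. A long-lived part of the Gas5 locus also stays open and was not tested. For the rises, inhibition of NMD by caffeine, a general retention of short-lived mRNAs and a weaker block of transcription stay open. All arrays had actinomycin D, and none of these causes was tested for the NMD-linked lists.

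The higher cAMP and CREB genes lay at percentile 100 of matched random lists, which argues against the span and level trend. A general retention of short-lived mRNAs would raise the inflammatory genes by about as much, if their mRNAs are short-lived. Of 31 above the median level, 14 rose and 13 fell. Their median was -0.0742, below the cAMP median by 1.00, more than the SD of 0.76 of their changes. Half-lives were not measured here, and not all of these mRNAs need be short-lived, so these values do not decide the question. Retention of short-lived mRNAs stays open, since 14 of 25 immediate early genes outside the cAMP list rose and 2 fell, with a median of 0.41. A weaker block of transcription while caffeine was present may also raise such genes and cannot be told apart from slower decay, because 0 of the 6 arrays lacked actinomycin D. Transcripts made in the first 4 hours of caffeine and lost after its removal are a further biological candidate that was not tested.

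For the lower granule and respiratory chain genes, the span and level trend is argued against by percentiles of 0.27 for the specific granule list and 0.85 for respiratory chain genes among matched random lists. A lower share of granulocytes would raise the markers of other cell types, but of 30 such markers above the median level, with those of eosinophils, basophils and mast cells left out, 21 fell and 3 rose, with a median of -0.50, although granulocytes also express some of them. In a relative fall, stable mRNAs look lower because short-lived mRNAs were kept. The lists were set against 28 ribosomal protein genes, whose mRNAs are stable (median -0.22, SD 0.34). These were above the median level and over 0.5 below the brightest Gas5 probe set. They included the ribosomal-like gene Rpl7l1 (log2 difference -1.10), which the list holds by its name. The specific granule median lay 0.396 below theirs, more than that SD. However, that SD is a spread across genes, and the full ribosomal list fell less than matched random lists (percentile 98.7). The gap therefore does not decide the question for the specific granule list. For respiratory chain genes the gap was 0.127, within that SD. A relative fall stays open for both lists.

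The count of changed genes was set against other groupings of the arrays. The real grouping gave 7554 genes and was the 1 split of 10 with as many, and the highest of the others gave 0. With 10 splits the share can never be under 0.05.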

How the results depend on the processing

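In this part, named genes are those chosen by the rule, since genes named outside it were not followed. Every named gene that was tested kept its direction under all alternatives run. Named genes kept their side of the threshold in 2543 comparisons, lost it in 8 and gained it in 8. The counts of genes higher and lower stayed within 1.5 times the main counts everywhere. With the replicate number as a block 3388 genes were higher and 4660 lower, and no named gene and no list changed its call; deviations of same-numbered arrays from their group means correlated at -0.03, 0.19 and 0.29, not all above 0.1, so the numbers were not taken as pairs. As a hint from the data, 4 of the 6 arrays correlated best with their own number, and the second principal component (7.19% of the variance) set both arrays numbered 3 (-11.3 and -16.0) apart from the others (3.09 to 10.3). Leaving out 1 array gave 2880 to 3238 genes higher, 3798 to 4364 lower, 449 to 590 higher and 585 to 706 lower by at least 2-fold, 12 to 15 lists higher and 7 to 9 lower. With 1 array left out the remaining 2 were assumed to vary like the other group. Testing every probe set gave 1240 higher and 976 lower by at least 2-fold, against 525 and 629 genes. Of these probe sets, 523 and 173 were unlisted ones numbered before the first listed one. With an estimated correlation 0 lists were higher and 0 lower by camera, and fry called 16 lower. Among genes above the median level 2 lists not called in either setting changed direction, p53 targets (adjusted p = 0.995) and erythroid markers (adjusted p = 0.667); the cause was not tested. With quantile normalization Gas5 passed at 0.14 on the log2 scale (adjusted p = 0.0046), and with the mean of its probe sets at 1.25 (adjusted p = 3.2e-09), since 3 of its 4 probe sets rose. Centring arrays on their medians moved the share of higher genes among the calls from 42.7% to 49.5%. Of the 7554 calls, 6627 to 7079 were kept with the same sign when an array was left out, 7151 after quantile normalization, 6978 with arrays centred and 6624 with every probe set tested; 2 were reversed with the mean of a gene's probe sets. In the self-test 56% of changes of 0.5 were recovered. Only 200 of 19937 genes were changed there, against 7554 calls here, which makes the adjusted threshold stricter in the self-test. That share therefore does not carry over to these data, where the share of missed changes of 0.5 was not measured.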

Other observations

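The name families and the span trend in this part were chosen after the values were seen, so they are described and not tested. Each family's median was set against 10000 random lists matched on bins of genomic span and mean level, and these percentiles are descriptions as well. They come from a look at 12 families, of which only some are described below. The others were genes named Fbxo, Olfr, Rab, Zc3h or Zcch, Psm, Rgs and Tas2r. Their percentiles were 99.2, 98.0, 11.7, 56.8, 53.8, 79.8 and 5.3, in that order.

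Histone lysine demethylase and methyltransferase genes (names beginning Kdm or Kmt) mostly rose, with 18 of 26 rising and none falling, against 3229 of all 19937 genes rising (percentile 97.7). Kdm3a differed by 1.79 ± 0.08 on the log2 scale, Kdm6a by 1.73 ± 0.14 and Kdm4c by 1.46 ± 0.09. Of 53 ubiquitin-specific protease genes (Usp) 26 rose and 6 fell (percentile 99.9), with Usp7 at 1.68 ± 0.05 and Usp48 at 1.32 ± 0.07, while Usp11 was lower at -1.27 ± 0.08. Mitochondrial ribosomal protein genes went the other way, with 40 of 77 lower and 13 higher, but their median did not stand apart from matched random lists (percentile 24.7). Mrps33 differed by -1.35 ± 0.07 and Mrpl51 by -1.24 ± 0.10, and Mrps30 was higher at 1.57 ± 0.09. Of 14 S100 genes 11 fell and none rose (percentile 0.25), with S100a6 at -2.22 ± 0.06 and S100a4 at -1.89 ± 0.06. Of 347 zinc finger genes named Zfp 145 fell and 51 rose (percentile 0), including Zfp599 at -2.08 ± 0.10. After quantile normalization the counts were 17 higher and 1 lower for Kdm and Kmt, 25 and 6 for Usp, 14 and 44 for mitochondrial ribosomal proteins, 0 and 11 for S100, and 55 and 139 for Zfp. With arrays centred on their medians they were 18 and 0, 26 and 5, 17 and 35, 0 and 11, and 58 and 130.

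The direction of change varied with the genomic span of a gene. With genes ordered by span in GRCm38.p6 and split into 10 bins, 5.47% were higher and 28.6% lower in bin 2 (median span 3.00 kb), against 30.8% higher and 13.1% lower in bin 9 (median 79.8 kb). In bin 1 (median 0.939 kb) 4.62% were higher and 11.3% lower, and in bin 10 (median 191 kb) 22.7% were higher and 6.38% lower. Log2 difference and span correlated at Spearman's rho = 0.19 across all 19918 genes with a span and at 0.35 across the 10636 of them above the median level; both are across genes, which are not independent replicates. The spans include introns, and transcript lengths were not used here.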
